A study of Cottus rhenanus and Cottus perifretum with 56 samples.

How the data were processed

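Whole-fish RNA of 56 sculpins (Cottus, small bottom-living freshwater fish) was hybridised to a custom one-colour Agilent array, 1 array per fish. Per the labels' protocols, each fish was homogenised whole, total RNA was extracted with Trizol and checked on an RNA chip, and Cy3-labelled cRNA was made with a low-input kit. Per the submitters' processing notes and the file headers, spot values came from Agilent Feature Extraction 10.7.3.1. The processed signal in the scanner output is, per the file headers, an intensity on a linear scale after background subtraction and detrending within the array, and it was not scaled between arrays. The flags for signal well above background, saturation and outlier spots came from the same files. A second source was a series-wide table of intensity values that, per the labels and the series text, the authors had calibrated for each probe, filtered for quality and divided by the 75th percentile of each array. In that deposited table the column medians lay between 0.253 and 0.293 and the 75th percentiles near 1, so its scale was linear, with no centring of probes visible. Its columns followed the scanner intensities of the same fish, with Spearman correlations across probes of at least 0.973, where probes are not independent replicates. The details of the authors' calibration were not given in the sources used here.

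Each array held 15744 spots, of which 536 were controls and 15208 belonged to 13329 probes of 60 bases. Of these probes, 11642 were printed once, 1663 were printed on 2 spots and 24 on 10 spots. Probes were identified by the array design's ID, by the assembled contig or single read each was made from, and by its sequence. The files pair no probe with a gene name and no reference annotation was used here, so the lists of genes written before the data were examined could not be tested and no gene is named. Saturated spots did not occur.

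The log2 of the processed signal was averaged over the spots of a probe, with outlier spots set missing, and the 75th percentile of each array was subtracted. A level of 0 therefore means a probe as bright as the 75th percentile of its array. A probe was tested if it was well above background on at least 0.5 of the arrays of at least 1 of the 9 groups, which kept 12940 probes and removed 389. Missing values numbered 312 over 169 of the tested probes. The groups were taken from the labels: 5 river populations and 4 laboratory F2 crosses. One linear model per probe was fitted to all 56 arrays with limma 3.58.1 in R 4.3.3, with a mean for each group and an additive term for rearing (wild or laboratory, as labelled), followed by empirical Bayes moderation. The 2 populations of a species, and the 4 crosses, were averaged with equal weight. A probe was called at a Benjamini-Hochberg adjusted p under 0.05 within each contrast, and every adjusted p printed here is of this kind. A probe was counted as outside both parents where it was called against each of them with the same sign, and as private to a population where it was called higher, or lower, than in each of the other populations.

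The position of Sieg and of the F2 between the species, from 0 at C. perifretum to 1 at C. rhenanus, was estimated over probes called between one pair of populations, with the difference of the other pair as the denominator. It was averaged over 4 such pairings, and its interval is the 95% range of 500 resamples of the fish within group and rearing. Where a probe was above background on 0 arrays of a group, a fold is given as a bound: the mean of the brighter group against, for each array of the dimmer group, the higher of the probe's own signal and the lowest signal among probes well above background. Where it was above background on part of the arrays of the dimmer group, the fitted change rests in part on background signal. The difference of measured means with the dimmer group raised in that way, not adjusted for rearing, is then given as the floored difference. For rearing it is wild minus laboratory-reared, averaged over Broel, Naaf and Sieg or within one of them. The rule for named probes was fixed before the data were examined: as the files give no gene names, the 2 probes with the largest rise and the 2 with the largest fall among the called probes of each main comparison, with the smaller of the 2 changes deciding for the comparisons against both parents. Levels of named probes are means ± SD over fish as measured, while changes are ± SE from the model and adjusted for rearing, so the measured means and the fitted changes can differ.

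The number of fish limits the precision of every value. The fish of a population were separate animals with 1 array each. On the 24 probes printed on 10 spots, the median SD between spots of an array was 0.06 on the log2 scale. In data simulated from the measured means and spreads over 12771 probes, the species contrast recovered 76.1% of 67 probes changed 2-fold and 93.9% of 66 probes changed 4-fold. The same figures were 64.2% and 90.9% for Sieg outside both parents, and 85.1% and 98.5% for rearing. The simulated noise was normal and independent for each probe and fish. It held no spread shared between probes and no likeness between fish of a group, so these rates need not hold for the measured fish. The files give 8 slides, 8 array positions on each slide and 3 scan days, which are numbered here without dates.

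The alternatives fixed before the data were examined were normexp background correction with an offset of 50, quantile normalization, the authors' table (log2 of the value plus 0.01, for the 7405 tested probes it holds), scanner values of those same probes, no filter on dim probes, no rearing term, laboratory-reared fish alone, slide as a block, population or cross as a random block with an estimated correlation of 0.189, the number in the sample title as a block, each F2 fish left out, and each parental population or cross left out. Chosen after seeing the data were a score for the main axis of spread within groups (as a covariate, or in place of the rearing term), a floor common to all arrays, array position as a block, the removal of the 4 arrays with the fewest detected probes, and fits without scan day 3 or within a scan day. The axis score is the projection of each fish on the first singular vector of the residuals from group and rearing. For the chance of each count, group labels were shuffled among the fish compared, 100 splits with the real one included. No 2 arrays correlated above 0.993 over the tested probes, and all fish were kept.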

Results

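The arrays measured probe signal for transcripts in whole fish of the invasive sculpin lineage of the river Sieg, which arose by hybridisation. Its parental species C. rhenanus and C. perifretum, and F2 crosses made between them in the laboratory, were measured alongside. Whether each probe sequence matches both species equally was not tested, so a difference in signal need not be one in transcript level. The stated subject of the series is how the transcriptome differs after admixture of whole genomes. C. rhenanus was represented by the populations Broel and Naaf and C. perifretum by Laarse Beek and Witte Nete, with 8 fish each, and the invasive lineage by 8 fish from the Sieg. The crosses ZG11 and ZG46B descended from Broel and Witte Nete and the crosses ZG38 and ZG39 from Naaf and Laarse Beek, with 4 fish each. Wild-reared fish were found only in Broel (2 of 8), Naaf (6 of 8) and Sieg (6 of 8), and all other fish were laboratory-reared.

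Between 9920 and 13017 of the 13329 probes were well above background on an array, with a median of 12005. The 75th percentile of the processed intensity ranged from 1731 to 4195. The 2 laboratory-reared Sieg fish had 10819 and 9920 detected probes, against 11625 to 12829 in the 6 wild ones. Array position followed the groups: all 6 wild Sieg fish lay at position 1 and both laboratory-reared ones at position 8. In Naaf all 6 wild fish lay at position 3 and both laboratory-reared ones at position 2. Scan day 3 held only Broel (4 fish) and Laarse Beek (5 fish). On scan day 1 all C. rhenanus and Sieg fish were wild and all C. perifretum and F2 fish laboratory-reared, so the fits within it cannot part differences between these sets of groups from rearing. One axis held 50.8% of the spread between fish within groups and the next 6.55%. Along it the fish fell into separate sets, 24 between -83.2 and -35.8 and 32 between 30.0 and 80.2. The higher set held 3 of 8 Broel, 5 of 8 Naaf, 2 of 8 Laarse Beek, 5 of 8 Witte Nete and 7 of 8 Sieg fish, and 2, 1, 3 and 4 of the 4 fish of ZG11, ZG46B, ZG38 and ZG39. It held 2 of 2 wild and 1 of 6 laboratory-reared fish in Broel, 5 of 6 and 0 of 2 in Naaf, and 5 of 6 and 2 of 2 in Sieg (exact conditional test within the populations, two-sided p = 0.0402).

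**Figure D1:**
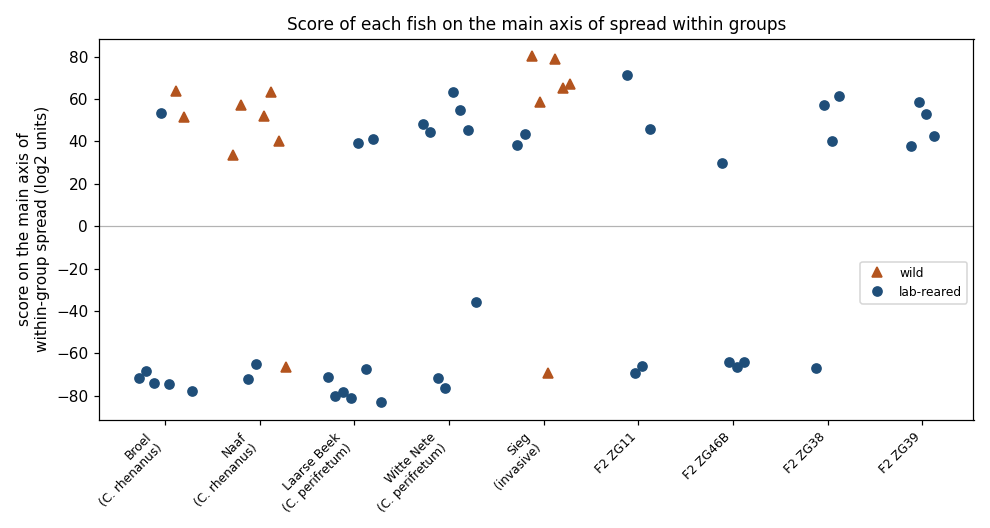
Score of each fish (vertical axis, log2 units summed over probes) on the main axis of spread within groups, by population or cross (horizontal axis); triangles are wild and circles laboratory-reared fish. No fish scored between -35.8 and 30.0, and 7 of the 8 Sieg fish and all 4 fish of ZG39 lay above 0.

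The comparison of the parental species found differences at 4190 of 12940 probes (32.4%), 2298 of them higher in C. rhenanus and 1892 higher in C. perifretum. The probe CUST_1964_PI425378899 (contig02769, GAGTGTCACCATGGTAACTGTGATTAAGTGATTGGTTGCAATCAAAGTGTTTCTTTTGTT) was bright in every C. rhenanus fish, at 1.22 ± 0.25 (SD, n = 16), and lay at -8.56 ± 1.11 (n = 16) in C. perifretum, where 1 of 16 arrays measured it above background. The fitted difference was 9.89 ± 0.63 (SE) on the log2 scale (adjusted p = 3.1e-17), set against background signal, and the floored difference was 7.95. The probe CUST_1170_PI425394527 (contig26230, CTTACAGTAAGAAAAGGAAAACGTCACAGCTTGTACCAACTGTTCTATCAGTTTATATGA) was above background in 9 of 16 C. rhenanus fish and in 0 of 16 C. perifretum fish, a mean level at least 24.3-fold higher in C. rhenanus (adjusted p = 0.000253). This difference was not called in 2 of 21 alternatives. In the opposite direction, CUST_7050_PI425378899 (contig07679, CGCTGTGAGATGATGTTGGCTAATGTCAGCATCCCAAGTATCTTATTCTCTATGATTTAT) was at least 158-fold higher in C. perifretum, at -0.02 ± 0.23 (n = 16) there, and was not well above background in any of the 16 C. rhenanus fish (adjusted p = 3.73e-14).

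The probe CUST_5721_PI425378899 (contig12604, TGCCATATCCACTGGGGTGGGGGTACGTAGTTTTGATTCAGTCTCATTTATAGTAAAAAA) lay at 2.53 ± 0.34 in C. perifretum and -7.62 ± 0.68 in C. rhenanus, with 6 of 16 C. rhenanus arrays above background, a fitted change of -11.60 ± 1.33 (adjusted p = 1.45e-09) and a floored difference of -9.70. Such large differences were few. By fitted changes, which rest in part on background signal, 24 probes were over 16-fold higher in C. rhenanus and 32 in C. perifretum, and 1108 of the called probes differed over 2-fold. From measured means with the dimmer species raised to the floor, not adjusted for rearing, these counts were 19, 23 and 854. At 1102 probes all 4 comparisons of a C. rhenanus with a C. perifretum population were called with one direction, 597 higher in C. rhenanus and 505 higher in C. perifretum. In the admixed fish the 4 named probes were mostly either near the bright parent's level or near background. CUST_1964_PI425378899 was above background in 8 of 8 Sieg and 14 of 16 F2 fish, and CUST_7050_PI425378899 in 8 of 8 and 11 of 16. With slide as a block 4186 probes were called, and within scan days 1, 2 and 3 the counts were 3085 (wild C. rhenanus against laboratory-reared C. perifretum, not separable from rearing), 1768 and 3508 (Broel against Laarse Beek alone). With array position as a block the count was 648, and with population as a random block it was 1569.

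**Figure D2:**
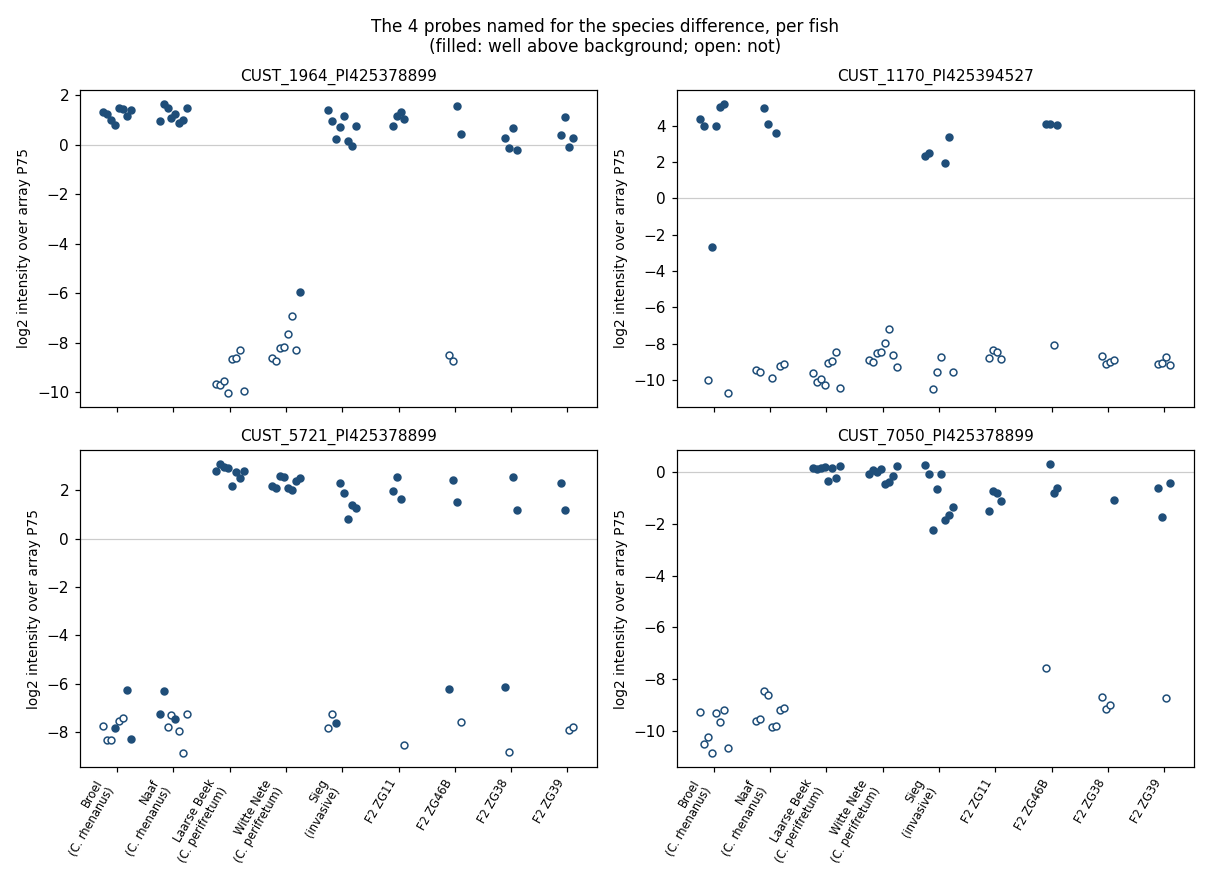
Level of the 4 probes named for the species difference (vertical axes, log2 intensity over the 75th percentile of the array) in each fish of the 9 groups (horizontal axis); filled points were well above background and open points were not. F2 fish of one cross often lay at either the bright or the dim level, with CUST_7050_PI425378899 above background in 11 of 16 F2 fish.

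Populations of one species differed less often in C. rhenanus than the species did. Between Broel and Naaf 479 probes were called, 171 higher in Broel and 308 higher in Naaf. Between Laarse Beek and Witte Nete 2350 were called, 1471 higher in Laarse Beek. Counts between populations of different species ran from 2808 (Laarse Beek against Naaf) to 3990 (Broel against Witte Nete). Sieg differed from Broel at 1583 probes, from Naaf at 3067, from Laarse Beek at 1558 and from Witte Nete at 850. Slide as a block lowered the Laarse Beek to Witte Nete count to 754 and the Broel to Naaf count to 244, and with array position as a block they were 271 and 269. Within scan day 1 the counts were 103 and 46, and within scan day 2 they were 59 and 105, with few fish.

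The invasive lineage was compared with each parental species to find probes whose level it shares with one of them or with neither. Sieg differed from C. rhenanus at 2810 probes (1155 higher and 1655 lower in Sieg) and from C. perifretum at 919 (401 higher and 518 lower). The contrasts were not equally precise: for CUST_3173_PI425378893 the SE was 0.81 against C. rhenanus and 1.01 against C. perifretum. These counts alone therefore do not show which species Sieg is nearer to. At 268 probes Sieg lay outside both species, 66 above and 202 below. The probe CUST_4331_PI425378893 (contig17897, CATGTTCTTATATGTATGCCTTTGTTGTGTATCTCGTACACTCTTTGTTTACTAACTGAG) was bright in all 8 Sieg fish, at 4.12 ± 0.96 (SD, n = 8). It was above background in 2 of 16 C. rhenanus fish (-8.73 ± 0.85) and in 8 of 16 C. perifretum fish (-4.46 ± 5.50), so some C. perifretum fish carried it at a high level too.

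Its fitted changes were 13.11 ± 1.59 against C. rhenanus (adjusted p = 1.63e-08) and 9.38 ± 1.98 against C. perifretum (adjusted p = 0.00159), and the floored differences were 11.32 and 7.57. The probe CUST_1803_PI425378899 (contig01105, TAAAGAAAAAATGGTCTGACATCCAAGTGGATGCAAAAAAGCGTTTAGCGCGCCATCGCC) lay at -1.32 ± 2.25 in Sieg, -4.83 ± 0.53 in C. rhenanus and -3.03 ± 0.49 in C. perifretum, and its rise over the nearer parent was 2.48 ± 0.51. Below both parents, CUST_3173_PI425378893 (contig05275, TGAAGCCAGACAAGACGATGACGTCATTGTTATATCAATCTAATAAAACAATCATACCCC) was above background in 2 of 8 Sieg fish (-6.49 ± 4.88) and in every fish of C. rhenanus (2.20 ± 0.45) and C. perifretum (1.42 ± 1.01). Its changes were -8.16 ± 0.81 and -6.33 ± 1.01 (adjusted p = 1.28e-10 and 3.28e-05), with floored differences of -7.03 and -6.25. CUST_465_PI425394527 (contig08827, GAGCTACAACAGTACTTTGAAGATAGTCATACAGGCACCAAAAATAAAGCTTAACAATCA) was above background in 4 of 8 Sieg fish and in every parental fish, with changes of -3.27 ± 0.46 and -2.96 ± 0.58 and floored differences of -2.44 and -2.16.

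Against C. perifretum the changes were not called in 4 of 20 alternatives for CUST_4331_PI425378893, 5 for CUST_1803_PI425378899, 1 for CUST_3173_PI425378893 and 3 for CUST_465_PI425394527, and against C. rhenanus in 0, 1, 1 and 2 in that order. None of these 4 probes was among those in the authors' deposited table, which held 57.2% of the probes tested. The count outside both parents was 1843 without the rearing term, 652 without the 4 arrays of fewest detected probes, which include both laboratory-reared Sieg fish, and 77 without Naaf. It was 215 with slide as a block, 261 and 20 within scan days 1 and 2, 22 with array position as a block and 9 with population or cross as a random block. The counts against C. rhenanus and C. perifretum were 2629 and 733 with slide as a block, 589 and 2611 within scan day 1 (no rearing term) and 1390 and 107 within scan day 2, 3920 and 5595 without the rearing term, 3192 and 3785 with the axis score in its place and 121 and 230 with array position as a block. The order of the counts turned in the last 3 of these and in scan day 1, and with the random block the counts were 359 and 50.

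The F2 crosses were laboratory hybrids of the same parental species. They differed from C. rhenanus at 3506 probes (1369 higher and 2137 lower in F2) and from C. perifretum at 4122 (1702 higher and 2420 lower), and lay outside both at 818, of which 201 were above and 617 below. The probes with the largest such changes were dim. Below both parents, CUST_3323_PI425378893 (contig02282, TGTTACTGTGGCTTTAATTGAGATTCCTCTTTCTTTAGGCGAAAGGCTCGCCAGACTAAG) was above background in 1 of 16 F2 fish (-7.53 ± 0.72), against 16 of 16 C. rhenanus fish (-5.64 ± 0.92) and 10 of 16 C. perifretum fish (-6.40 ± 0.74). Its changes were -1.75 ± 0.31 and -1.13 ± 0.26 (adjusted p = 6.57e-05 and 0.000871), with floored differences of -0.87 and -0.11, and with a floor common to all arrays the change against C. perifretum was 0 and not called.

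The probe CUST_2947_PI425378899 (contig09389, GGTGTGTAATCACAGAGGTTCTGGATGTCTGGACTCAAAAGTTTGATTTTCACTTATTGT) lay at -6.73 ± 1.82 in F2 (6 of 16 fish above background), -4.44 ± 0.37 in C. perifretum (16 of 16) and -4.91 ± 4.93 in C. rhenanus (7 of 16). Its change was -2.28 ± 0.66 against C. perifretum and -2.65 ± 0.79 against C. rhenanus, where it turned to 2.10 without Broel. Its floored differences were -1.48 and -1.01, and in the authors' table its change against C. perifretum was 0 and not called. Above both parents, CUST_1012_PI425394527 (contig22307, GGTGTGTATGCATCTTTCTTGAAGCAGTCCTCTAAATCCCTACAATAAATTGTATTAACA) changed by 2.62 ± 0.82 and 2.20 ± 0.68 and CUST_7305_PI425378899 (contig12214, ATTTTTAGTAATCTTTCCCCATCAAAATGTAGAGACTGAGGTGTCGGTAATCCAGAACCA) by 2.83 ± 0.79 and 1.84 ± 0.66 against C. rhenanus and C. perifretum. The floored differences were -0.04 and 1.21 for the former and 0.56 and 1.02 for the latter. Both probes followed the axis of spread within groups, with the ranks 165 and 164 by weight among 12771 probes. With the axis score as a covariate the change of CUST_1012_PI425394527 against C. rhenanus was 0.90 and no longer called, and within scan day 1, where all C. rhenanus fish were wild and all F2 fish laboratory-reared, the changes of these 2 probes against C. rhenanus were -1.61 and -1.23, a turn that cannot be told apart from rearing. Against C. rhenanus the change was not called in 12 of 40 alternatives for CUST_1012_PI425394527 and 7 of 40 for CUST_7305_PI425378899, and in 7 of 42 for CUST_2947_PI425378899 and 1 of 42 for CUST_3323_PI425378893, and against C. perifretum in 8, 12, 9 and 4 in that order. The count outside both parents was 397 with that covariate, 345 with slide as a block, 170 and 3 within scan days 1 and 2, 8 with array position as a block and 21 with population or cross as a random block. The counts against C. rhenanus and C. perifretum were 2006 and 3447 with slide as a block, 1980 and 941 within scan day 1, 916 and 221 within scan day 2, 33 and 2352 with array position as a block and 488 and 633 with the random block.

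Groups of 8 fish were then compared, each cross type with its own parental populations and Sieg with the same populations. The F2, Laarse Beek and Witte Nete fish were all laboratory-reared, while 6 of 8 Sieg, 6 of 8 Naaf and 2 of 8 Broel fish were wild. Both the F2 and the Sieg counts therefore rest on the rearing term. Against Broel and Witte Nete, the F2 of ZG11 and ZG46B lay outside both at 103 probes (61 above, 42 below) and Sieg at 135 (34 above, 101 below). Against Naaf and Laarse Beek, the F2 of ZG38 and ZG39 lay outside both at 1679 (694 above, 985 below) and Sieg at 437 (101 above, 336 below). The deviation of the F2 from the mean of their own parents differed between the cross types at 2314 probes. With the axis score as a covariate the F2 counts were 210 and 284, the Sieg counts 231 and 445, and the interaction was called at 278 probes. With slide as a block the F2 counts were 92 and 352, within scan day 1 they were 84 and 63 and within scan day 2 they were 23 and 4, where Laarse Beek had 1 fish. Without the rearing term the F2 counts were 93 and 768 and the Sieg counts 1052 and 1086, so the order of F2 and Sieg against Naaf and Laarse Beek turned. That order also turned with the axis score as a covariate and within scan day 1. It turned with array position as a block too, where both counts were far lower. The Sieg counts were 111 and 240 with slide as a block, 64 and 227 within scan day 1 and 43 and 4 within scan day 2. Leaving out ZG38 replicate 4 lowered the count of the Naaf by Laarse Beek crosses to 1032.

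**Figure D3:**
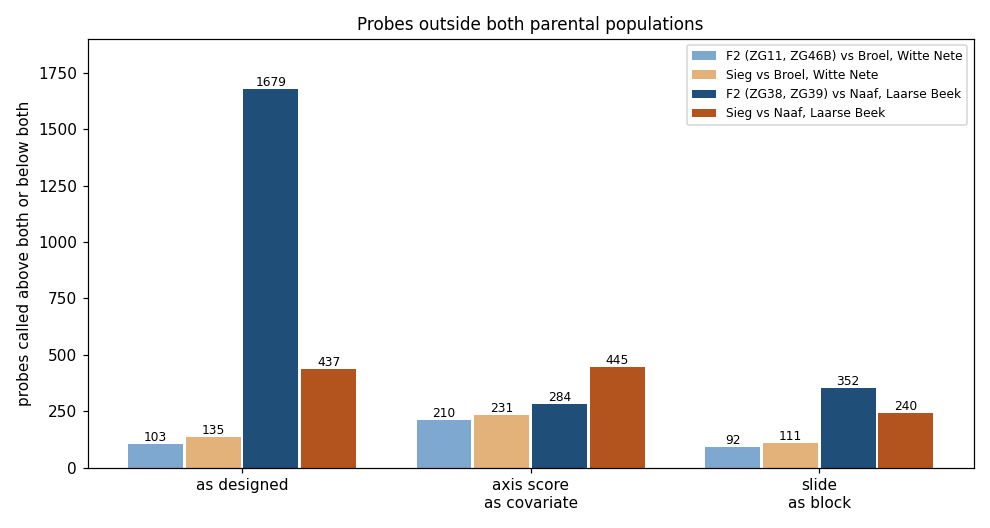
Number of probes (vertical axis) at which 8 F2 fish or 8 Sieg fish were called above both or below both of the 2 parental populations named in the key, under the designed fit, with the axis score as a covariate and with slide as a block (horizontal axis). The F2 count against Naaf and Laarse Beek was 1679 in the designed fit, 284 with the axis score and 352 with slide as a block.

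The direct comparison of Sieg with the F2 asked how the natural hybrid lineage differs from recent hybrids. It called 640 probes, 324 higher and 316 lower in Sieg. CUST_4331_PI425378893, the probe above both parents in Sieg, was higher by 6.65 ± 1.98 (adjusted p = 0.0375; floored 5.29) and was above background in 11 of 16 F2 fish. CUST_606_PI425378893 (contig05113, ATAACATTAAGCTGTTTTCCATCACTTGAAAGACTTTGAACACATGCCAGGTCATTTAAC) lay at -0.67 ± 0.84 (SD, n = 8) in Sieg and -4.99 ± 2.77 (n = 16) in F2, where 8 of 16 fish measured it, a change of 6.01 ± 1.42 (adjusted p = 0.00675; floored 3.94). For CUST_606_PI425378893 the parental populations lay at -2.30 (Broel), -4.91 (Naaf), -0.37 (Laarse Beek) and -4.78 (Witte Nete). Its wild fish lay below the laboratory-reared ones in C. rhenanus (-5.70 and -1.51) but above them in Sieg (-0.45 and -1.36). The fitted change, adjusted by 1 rearing term for all populations, was larger than the measured difference. CUST_3173_PI425378893 changed by -6.57 ± 1.01 (adjusted p = 2.66e-05; floored -6.49), with F2 fish at 1.66 ± 0.87.

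CUST_989_PI425378893 (contig23115, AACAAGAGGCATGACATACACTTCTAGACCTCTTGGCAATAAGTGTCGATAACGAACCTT) lay at -5.89 ± 2.41 in Sieg (4 of 8 fish above background) and -1.46 ± 1.79 in F2, a change of -5.02 ± 0.82 (adjusted p = 7.88e-05; floored -3.61), with 0.20 ± 0.29 in C. rhenanus and -3.86 ± 1.53 in C. perifretum. The count was 3338 without the rearing term, 1186 with the axis score as a covariate and 343 with slide as a block. It was 1987 and 256 within scan days 1 (no rearing term) and 2, 34 with array position as a block and 44 with population or cross as a random block. Of the named changes, that of CUST_4331_PI425378893 was not called in 12 of 40 alternatives, CUST_606_PI425378893 in 7 of 40, CUST_3173_PI425378893 in 2 of 40 and CUST_989_PI425378893 in 1 of 42, with no change of direction.

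Probes that set one population apart from every other were counted for each. Sieg had 69, of which 51 were lower, and Broel had 77, Naaf 136, Laarse Beek 295 and Witte Nete 210. The order of Sieg and Broel turned in several alternatives, among them quantile normalization (88 and 82) and slide as a block (54 and 43). It also turned without the rearing term (443 and 158), in laboratory-reared fish alone (91 and 66) and with the title number as a block (48 and 42). The Sieg count was 0.399 of the median of the parental counts. That ratio was 1.99 without the rearing term, 0.973 in laboratory-reared fish alone and 2.20 without the 4 arrays of fewest detected probes, which left Sieg with wild fish alone. With slide as a block it was 0.535, within scan day 1 it was 1.14, and within scan day 2, with 1 Laarse Beek fish, limma called 0 probes private to Sieg (55 at an unadjusted p under 0.05 in every contrast).

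Among the 4190 probes that differed between the species, Sieg was called different from C. rhenanus alone at 1590 (37.9%) and from C. perifretum alone at 511 (12.2%). It lay between both at 84, outside both at 55 and was called different from neither at 1950 (46.5%). The shares different from C. rhenanus alone and C. perifretum alone turned to 24.8% and 41.5% without the rearing term, to 26.0% and 32.5% with the axis score in its place and to 8.23% and 43.3% within scan day 1. They were 36.3% and 10.4% with slide as a block, 41.4% and 4.36% within scan day 2, and 10.5% and 10.2% with array position as a block, and with the random block the share different from C. perifretum alone was 2.17%. The F2 had more fish, and unlike for Sieg the SE was smaller against C. perifretum (0.68 for CUST_1012_PI425394527) than against C. rhenanus (0.82). The shares different from one species alone therefore also reflect precision. The F2 were different from C. perifretum alone at 1503 (35.9%), from C. rhenanus alone at 1382 (33.0%), between both at 505, outside both at 37 and different from neither at 763 (18.2%). The F2 shares different from C. perifretum alone and C. rhenanus alone were 38.1% and 23.8% with slide as a block and turned to 16.6% and 39.6% within scan day 1, to 8.43% and 32.5% within scan day 2 and to 23.5% and 39.8% without Laarse Beek. Their order also turned, by less, without ZG11 (33.27% and 34.45%) and with the axis score in place of the rearing term (30.34% and 33.49%). It turned slightly with the random block (20.01% and 20.2%), and without ZG38 both shares were 32.28%. The share of F2 outside both, 0.883%, was 0.541% without ZG11 replicate 1, 0.574% without ZG11 replicate 4, 0.572% without ZG46B replicate 1 and 1.37% without ZG38 replicate 1. The position of Sieg on the line from C. perifretum (0) to C. rhenanus (1) was 0.324 (95% interval 0.260 to 0.389) and that of the F2 0.386 (0.325 to 0.439). The difference of Sieg minus F2 was -0.0614 (-0.105 to -0.00798). Its direction turned without the rearing term, where the positions of Sieg and the F2 were 0.486 and 0.447, and without the 4 arrays of fewest detected probes, where they were 0.516 and 0.399. In laboratory-reared fish alone, with 2 Sieg fish, they were 0.127 and 0.345. The positions of Sieg and the F2 were 0.372 and 0.422 with slide as a block, 0.723 and 0.448 within scan day 1 (no rearing term), where the direction also turned, and 0.356 and 0.414 within scan day 2.

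Rearing was estimated within Broel, Naaf and Sieg and was called at 5039 probes, 2521 higher and 2518 lower in wild fish. CUST_2409_PI425378899 (contig22389, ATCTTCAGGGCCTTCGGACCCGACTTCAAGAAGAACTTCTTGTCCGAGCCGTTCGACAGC) fell by 4.34 ± 0.51 (adjusted p = 6.48e-09; floored difference -4.07), and CUST_2928_PI425378899 (contig15798, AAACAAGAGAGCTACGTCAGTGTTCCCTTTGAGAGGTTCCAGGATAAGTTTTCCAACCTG) fell by 4.27 ± 0.59 (adjusted p = 2.5e-07; floored difference -4.17). In C. rhenanus the former lay at -0.01 ± 0.46 in 8 laboratory-reared fish and -3.92 ± 2.35 in 8 wild fish, and the latter at 0.23 ± 0.37 and -4.08 ± 2.50. In Sieg the former lay at -1.84 ± 0.02 in 2 laboratory-reared and -4.83 ± 1.88 in 6 wild fish.

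The largest rises were CUST_3747_PI425378893 (contig26166, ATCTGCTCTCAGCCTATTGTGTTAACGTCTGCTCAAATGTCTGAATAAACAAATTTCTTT), at 6.81 ± 2.37 (adjusted p = 0.0205; floored difference 5.92), and CUST_1161_PI425378893 (contig26827, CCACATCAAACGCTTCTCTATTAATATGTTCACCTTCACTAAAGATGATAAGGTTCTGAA), at 6.70 ± 2.20 (adjusted p = 0.0148; floored difference 6.01). Their levels spread over many log2 units in every lineage, with SDs of 6.55 and 6.32 in C. rhenanus and 5.83 and 5.44 in C. perifretum, and they ranked 7 and 23 by weight on the axis of spread within groups. Fitted within populations, their changes were -0.67 and -0.61 in Sieg and rises of at least 8.49 and 8.73 in Naaf, where 0 of 2 laboratory-reared fish were above background for either probe, and none of these changes was called. In Broel the change of CUST_1161_PI425378893 was 10.28 and called (adjusted p = 0.0425; floored difference 9.92, with 3 of 6 laboratory-reared fish above background), that of CUST_3747_PI425378893 was a similar rise and not called, and the differences between populations were not called for either probe. With the axis score as a covariate the pooled changes were 0.01 and 0.36, neither called, and 2753 probes were called for rearing. Each of these 2 changes was not called in 6 of 16 alternatives, and the 2 falls were called in all. Over the probes tested, rearing fitted within each population was called at 2485 probes in Broel, 1003 in Naaf and 2179 in Sieg, and with the axis score as a covariate at 1486, 496 and 3780, so that the order of Broel and Sieg turned. The change differed between Naaf and Broel at 110 probes, between Sieg and Broel at 699 and between Sieg and Naaf at 473, and with the axis score at 316, 1627 and 1561. With slide as a block 3378 probes were called, and 1581 within scan day 2. The other scan days held no population with both rearings. The fits within populations rest on 2 wild fish in Broel and on 2 laboratory-reared fish each in Naaf and Sieg. In Broel both wild fish were scanned on day 1 and the laboratory-reared fish on days 2 and 3. The Broel rearing change therefore cannot be parted from scan day and slide. Those of Naaf and Sieg cannot be parted from array position, as wild and laboratory-reared fish shared no position in either. The differences between populations in the rearing change share these limits.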

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

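The tests of slides, of rearing along the axis, of the axis score and of slide as a block reported in this part were chosen after the patterns were seen. Dixon's test for a single fish far from its group was applied to the 18 named probes in each of the 9 groups. Its 95% limit was passed in 25 of 162 cases, 15.4%, where normally spread values give about 1 in 20. The named probes were picked for large changes, so that rate is not a fair mark for them.

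Most of these fish belonged to the F2 crosses, and several lay at a bright level with the rest dim, or the reverse. The test marks a single fish, so in a cross of 4 it can find only splits of 3 against 1. CUST_1170_PI425394527 was at -8.08 in ZG46B replicate 3 with the nearest fish of that cross at 4.07, and CUST_5721_PI425378899 was at -8.54 in ZG11 replicate 4 with the nearest at 1.66. CUST_7050_PI425378899 was at -1.08 in ZG38 replicate 4 (nearest -8.67), at -8.72 in ZG39 replicate 3 (nearest -1.73) and at -7.57 in ZG46B replicate 1 (nearest -0.80). CUST_4331_PI425378893 was at -8.83 in ZG38 replicate 3 (nearest 1.26) and at -8.59 in ZG39 replicate 3 (nearest 0.64). CUST_606_PI425378893 was at -1.04 in ZG46B replicate 1 (nearest -6.34). Smaller gaps were found for CUST_3173_PI425378893 in ZG11 replicate 3 (0.54) and ZG46B replicate 4 (1.64) and for CUST_989_PI425378893 in ZG11 replicate 1 (0.22).

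The probes that followed the main axis of spread gave another group of such values. CUST_3747_PI425378893 was at -5.74 in Sieg replicate 5, -8.40 in ZG38 replicate 1 and 3.16 in ZG46B replicate 1. CUST_1161_PI425378893 was at -5.35, -6.29 and 3.35 in the same fish. CUST_7305_PI425378899 was at -8.28 in Sieg replicate 5 and -8.42 in ZG38 replicate 1, and CUST_1012_PI425394527 was at -8.42 in ZG38 replicate 1. These 3 fish were the only ones of their groups on their side of 0 on the axis. In the populations, CUST_2947_PI425378899 was at -9.52 in Broel replicate 3 (nearest -0.92) and CUST_989_PI425378893 at -0.44 in Sieg replicate 8 (nearest -5.12). Closer to their groups were CUST_5721_PI425378899 at -6.27 and CUST_989_PI425378893 at 0.41 in Broel replicate 4, and CUST_2928_PI425378899 at 0.68 in Witte Nete replicate 4.

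The first pattern weighed is the division of the fish into separate sets on the axis. Slides were argued against as the whole cause, because all 7 slides with 7 or 8 arrays held fish of both sets. The sets were not spread evenly, however. Most fish of scan day 1 lay above 0, and on scan day 3 all but Broel replicate 12 (53.3) lay below it. A part played by slide or scan day was not tested. Dim probes and scaling were argued against, because over the 9182 probes above background on every array the axis still held 40.0% of the within-group spread, and 51.4% over all probes under quantile normalization, against 50.8% in the designed fit. The division also ran within the laboratory-reared fish, of which 47.6% (20 of 42) lay above 0. The axis was, however, sought after the rearing term was fitted, so this could not have come out for rearing as the whole cause. Rearing went with the side over the 3 populations Broel, Naaf and Sieg as a whole (exact conditional test within the populations, two-sided p = 0.0402). No single population passed (Fisher's exact test, two-sided p = 0.107, 0.107 and 1), but with so few fish on one side none could. In Broel and Naaf the split by rearing was the most extreme that their counts allowed. Rearing could not be parted from scan day in Broel, nor from array position in Naaf and Sieg. The labels give no sex, maturity or season, so other biological explanations were not tested.

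The second pattern is the rise of the Sieg count outside both parents from 268 to 1843 without the rearing term. If wild Sieg fish share a response to rearing with wild C. rhenanus, the sign of Sieg minus C. perifretum should match wild minus laboratory in C. rhenanus alone. It matched at 89.7% of the 1843 probes and at 72.5% of all probes, which is in line with that explanation. An unequal mix of the 2 sets of fish was argued against as the whole cause, since with the axis score in place of the rearing term the count was still 855. Among those 855 probes the signs matched at 70.3% once the score was in both fits, against 58.8% of all probes, so the shared response stays open. Array position, which parts wild from laboratory-reared fish in Sieg and in Naaf, cannot be separated from it there.

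Rearing changes that differed between populations were found at 110 probes for Naaf against Broel, 699 for Sieg against Broel and 473 for Sieg against Naaf, each by the interaction. These counts depended on the axis, being 316, 1627 and 1561 with the axis score as a covariate. Of the named probes, CUST_2409_PI425378899 changed by 4.53 less in Naaf and 4.30 less in Sieg than in Broel, where it fell most, and CUST_2928_PI425378899 by 5.14 less in Sieg than in Broel (adjusted p = 0.0147, 0.00834 and 0.00901). In Broel 1 of 2 wild fish was above background for either probe, so these differences rest in part on background signal. Both wild Broel fish were scanned on a day without laboratory-reared Broel fish, so the Broel change cannot be parted from scan day and slide. The Naaf and Sieg changes cannot be parted from array position.

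The third pattern is the larger F2 count in the Naaf by Laarse Beek crosses, 1679 against 103, with a deviation from the parents that differed between the cross types at 2314 probes. CUST_1012_PI425394527 and CUST_7305_PI425378899 were among these, with differences of -3.57 and -3.44 between the Broel by Witte Nete and the Naaf by Laarse Beek crosses (adjusted p = 0.0372 and 0.0371). Of the 4 arrays with the fewest detected probes, none is of an F2, Naaf or Laarse Beek fish and 2 are of Witte Nete, so they can act mainly through the smaller count. That was argued against, since this count was 131 and the ratio of the counts 13.4 without them, against 103 and 16.3 with them. An unequal mix of the 2 sets of fish could account for it, since with the axis score as a covariate the ratio was 1.35, and ZG38 and ZG39 had 7 of 8 fish in the higher set where Laarse Beek had 2 of 8. Slide stays open, as the ratio was 3.83 with slide as a block. The cross types shared slides in part. Fish of ZG38 and ZG39 lay on slides 3, 4, 7 and 8 alone, and of the F2 fish, slides 5 and 6 held those of ZG11 and ZG46B alone. In addition, 5 of the 8 Laarse Beek fish were scanned on a day of their own with Broel, on slides without F2 fish. Without that day, scan day 3, the Naaf by Laarse Beek crosses kept the larger count, at a ratio of 6.77. The ratio was 3.74 in laboratory-reared fish alone, and it fell below 1 within scan day 1 (63 against 84) and to 0.174 within scan day 2, with few fish. On scan day 1 the C. rhenanus parents were wild and the F2 laboratory-reared, so the count there also holds rearing. The difference between the parents of the crosses was not tested apart from these.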

How the results depend on the processing

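The alternatives with the axis score, array position, a common floor, the 4 arrays left out and the scan days were chosen after the data were seen. Leaving out F2 fish cannot move an estimate that compares no F2 fish, so those fits are counted here for F2 comparisons alone. Of 804 refitted changes of named probes, 688 kept their direction and their side of the threshold, 111 kept their direction but were no longer called, 2 were at 0 and 3 reversed. The reversed ones were CUST_2947_PI425378899 against C. rhenanus in the F2, 2.10 without Broel, and CUST_1012_PI425394527 and CUST_7305_PI425378899 against C. rhenanus, -1.61 and -1.23 within scan day 1. The species difference stayed within 1.5 times its count in 16 of 23 alternatives, Sieg outside both parents in 10 of 22 and F2 outside both parents in 28 of 42. Signal over background limited the named F2 probes, which were dim, and leaving out the filter moved none of the counts by over 1.5 times. Where 4 fish make a cross, leaving out each F2 fish in turn gave 1032 to 2431 for F2 outside Naaf and Laarse Beek, lowest without ZG38 replicate 4 (1032). It moved the share of species-different probes with F2 outside both from 0.883% to 0.541% (ZG11 replicate 1), 0.574% (ZG11 replicate 4), 0.572% (ZG46B replicate 1) and 1.37% (ZG38 replicate 1), and no other count or share reported by over 1.5 times. For probes private to a population the share of higher ones moved by over 10 points in Laarse Beek after normexp (127 higher, 89 lower), Broel after quantile normalization (34 and 48) and Naaf with a common floor (95 and 57). Private counts moved by over 1.5 times in 10 of 17 alternatives for Broel, Witte Nete and Sieg and 11 of 17 for Naaf and Laarse Beek, and the share of species-different probes with Sieg different from one species alone in 7 of 22 for either species. The values below are those of the main counts, the private ratio and the positions that moved by over 1.5 times (positions by more than their SE), and the cause was not tested, except that the 2 settings limited to the 7405 deposited probes test fewer probes.

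The numbers in the sample titles do not pair the fish: the mean correlation of residuals was -0.0264 over 137 pairs with the same number and 0.0002 over 1239 other pairs, and 2 of 56 fish correlated best with a fish of their own number. As a block the number is among the alternatives here. Not run, as the fit leaves no estimate, were the random block for differences between populations, matched, private and position values, a population left out for its own contrasts, and rearing where rearing is not in the model or does not vary. The gene lists were not run under any setting.

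In the authors' table the calls numbered 2424 (species difference), 306 (Broel against Naaf), 1300 (Laarse Beek against Witte Nete), 2794 (rearing), 1618 (Sieg against C. rhenanus), 543 (Sieg against C. perifretum), 142 (Sieg outside both), 372 (Sieg against F2), 1964 (F2 against C. rhenanus), 2356 (F2 against C. perifretum), 453 (F2 outside both), 52 (F2 outside Broel and Witte Nete), 964 (F2 outside Naaf and Laarse Beek), 78 (Sieg outside Broel and Witte Nete) and 246 (Sieg outside Naaf and Laarse Beek). Among the laboratory-reared fish the calls numbered 1477 (Sieg against C. rhenanus), 460 (F2 outside Naaf and Laarse Beek) and 223 (Sieg outside Naaf and Laarse Beek). Among the laboratory-reared fish the position of Sieg was 0.127, the position of the F2 was 0.345 and the ratio of private probes was 0.973. Without the rearing term the calls numbered 866 (Broel against Naaf), 5595 (Sieg against C. perifretum), 1843 (Sieg outside both), 3338 (Sieg against F2), 768 (F2 outside Naaf and Laarse Beek), 1052 (Sieg outside Broel and Witte Nete) and 1086 (Sieg outside Naaf and Laarse Beek). Without the rearing term the position of Sieg was 0.486, the position of the F2 was 0.447 and the ratio of private probes was 1.99. After normexp correction the calls numbered 170 (Sieg outside both) and 53 (F2 outside Broel and Witte Nete). After normexp correction the position of the F2 was 0.420. Under the random block the calls numbered 1569 (species difference), 359 (Sieg against C. rhenanus), 50 (Sieg against C. perifretum), 9 (Sieg outside both), 44 (Sieg against F2), 488 (F2 against C. rhenanus), 633 (F2 against C. perifretum) and 21 (F2 outside both). With the title number as a block the calls numbered 252 (Broel against Naaf), 558 (Laarse Beek against Witte Nete), 1790 (F2 against C. rhenanus), 2184 (F2 against C. perifretum), 232 (F2 outside both), 50 (F2 outside Broel and Witte Nete), 525 (F2 outside Naaf and Laarse Beek) and 246 (Sieg outside Naaf and Laarse Beek). With the title number as a block the position of Sieg was 0.381 and the position of the F2 was 0.437. For scanner values of the deposited probes the calls numbered 2479 (species difference), 291 (Broel against Naaf), 1436 (Laarse Beek against Witte Nete), 2981 (rearing), 1702 (Sieg against C. rhenanus), 571 (Sieg against C. perifretum), 164 (Sieg outside both), 377 (Sieg against F2), 2119 (F2 against C. rhenanus), 2462 (F2 against C. perifretum), 518 (F2 outside both), 60 (F2 outside Broel and Witte Nete), 85 (Sieg outside Broel and Witte Nete) and 282 (Sieg outside Naaf and Laarse Beek). With slide as a block the calls numbered 244 (Broel against Naaf), 754 (Laarse Beek against Witte Nete), 343 (Sieg against F2), 2006 (F2 against C. rhenanus), 345 (F2 outside both), 352 (F2 outside Naaf and Laarse Beek) and 240 (Sieg outside Naaf and Laarse Beek). With slide as a block the position of Sieg was 0.372 and the position of the F2 was 0.422.

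Without Broel the calls numbered 2403 (species difference), 2864 (rearing), 1339 (F2 against C. rhenanus), 301 (F2 outside both) and 947 (F2 outside Naaf and Laarse Beek). Without ZG11 there were 236 (F2 outside Broel and Witte Nete). Without ZG39 the calls numbered 2144 (F2 against C. rhenanus), 372 (F2 outside both) and 506 (F2 outside Naaf and Laarse Beek). Without ZG39 the position of the F2 was 0.418. Without ZG46B there were 1502 (F2 outside both). Without Laarse Beek the calls numbered 1926 (F2 against C. perifretum) and 228 (F2 outside both). Without Naaf the calls numbered 3279 (rearing), 1185 (Sieg against C. rhenanus), 461 (Sieg against C. perifretum), 77 (Sieg outside both), 331 (Sieg against F2) and 63 (Sieg outside Broel and Witte Nete). Without Witte Nete the calls numbered 1552 (Sieg against C. perifretum) and 426 (Sieg outside both).

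With array position as a block the calls numbered 648 (species difference), 269 (Broel against Naaf), 271 (Laarse Beek against Witte Nete), 121 (Sieg against C. rhenanus), 230 (Sieg against C. perifretum), 22 (Sieg outside both), 34 (Sieg against F2), 33 (F2 against C. rhenanus), 2352 (F2 against C. perifretum), 8 (F2 outside both), 2 (F2 outside Broel and Witte Nete), 11 (F2 outside Naaf and Laarse Beek), 18 (Sieg outside Broel and Witte Nete) and 20 (Sieg outside Naaf and Laarse Beek). With array position as a block the position of the F2 was 0.325 and the ratio of private probes was 0.917. Under the axis score as a covariate the calls numbered 907 (Broel against Naaf), 2753 (rearing), 1527 (Sieg against C. perifretum), 1186 (Sieg against F2), 397 (F2 outside both), 210 (F2 outside Broel and Witte Nete), 284 (F2 outside Naaf and Laarse Beek) and 231 (Sieg outside Broel and Witte Nete). Under the axis score as a covariate the position of Sieg was 0.376 and the position of the F2 was 0.431. Once the axis score took the place of the rearing term, the calls numbered 6611 (species difference), 1356 (Broel against Naaf), 3785 (Sieg against C. perifretum), 855 (Sieg outside both), 3611 (Sieg against F2), 208 (F2 outside Broel and Witte Nete), 671 (F2 outside Naaf and Laarse Beek), 629 (Sieg outside Broel and Witte Nete) and 657 (Sieg outside Naaf and Laarse Beek). Once the axis score took the place of the rearing term, the position of Sieg was 0.422, the position of the F2 was 0.435 and the ratio of private probes was 0.743. With a common floor the position of the F2 was 0.415. Within scan day 1 (no rearing term) the calls numbered 46 (Broel against Naaf), 103 (Laarse Beek against Witte Nete), 589 (Sieg against C. rhenanus), 2611 (Sieg against C. perifretum), 1987 (Sieg against F2), 1980 (F2 against C. rhenanus), 941 (F2 against C. perifretum), 170 (F2 outside both), 63 (F2 outside Naaf and Laarse Beek), 64 (Sieg outside Broel and Witte Nete) and 227 (Sieg outside Naaf and Laarse Beek). Within scan day 1 (no rearing term) the position of Sieg was 0.723, the position of the F2 was 0.448 and the ratio of private probes was 1.14. Within scan day 2 the calls numbered 1768 (species difference), 105 (Broel against Naaf), 59 (Laarse Beek against Witte Nete), 1581 (rearing), 1390 (Sieg against C. rhenanus), 107 (Sieg against C. perifretum), 20 (Sieg outside both), 256 (Sieg against F2), 916 (F2 against C. rhenanus), 221 (F2 against C. perifretum), 3 (F2 outside both), 23 (F2 outside Broel and Witte Nete), 4 (F2 outside Naaf and Laarse Beek), 43 (Sieg outside Broel and Witte Nete) and 4 (Sieg outside Naaf and Laarse Beek). Within scan day 2 the ratio of private probes was 0, from 0 limma calls for Sieg and 55 at an unadjusted p under 0.05. Without scan day 3 the calls numbered 193 (Broel against Naaf), 351 (Laarse Beek against Witte Nete), 454 (Sieg against C. perifretum), 104 (Sieg outside both), 1862 (F2 against C. rhenanus), 2392 (F2 against C. perifretum), 208 (F2 outside both), 60 (F2 outside Broel and Witte Nete), 406 (F2 outside Naaf and Laarse Beek) and 93 (Sieg outside Naaf and Laarse Beek). Without scan day 3 the position of Sieg was 0.395 and the position of the F2 was 0.458. Without the 4 arrays of fewest detected probes the calls numbered 1363 (Laarse Beek against Witte Nete), 1431 (Sieg against C. perifretum), 652 (Sieg outside both), 1060 (Sieg against F2), 410 (Sieg outside Broel and Witte Nete) and 711 (Sieg outside Naaf and Laarse Beek). Without the 4 arrays of fewest detected probes the position of Sieg was 0.516 and the ratio of private probes was 2.20.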

Other observations

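The axis score used in this part and the probes singled out by detection were chosen after the data were seen. Probes that were above background in every fish of one species and in no fish of the other were rare. C. perifretum had 4 of them and C. rhenanus 1. In Sieg, 3 of the 4 C. perifretum probes were above background in all 8 fish and the other in 7. In the F2 they were measured in 10 to 14 of 16 fish, 71.9% on average, and the C. rhenanus probe was measured in 4 of 8 Sieg and 6 of 16 F2 fish. These probes were picked by their values in the parental fish, and the F2 and Sieg values had no part in the choice.

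Of the tested probes that were designed from single sequence reads, 12 came from C. perifretum reads, of which 7 were brighter in C. perifretum and 5 in C. rhenanus. Another 10 came from C. rhenanus reads, of which 6 were brighter in C. rhenanus and 4 in C. perifretum. In each of these sets 1 probe was called in each direction. A further 8 came from reads of the invasive lineage, of which 6 were brighter in C. perifretum and 2 in C. rhenanus, with none called in either direction.

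The spread between fish within the F2 crosses was larger at probes that differ between the species, a hypothesis set down before the test being that parental alleles segregate in the F2. Probes were chosen from one pair of populations (2045 to 4221 probes) and the spread of the parents was taken from the other pair. The variance within crosses was 1.51 times that within populations at species-different probes and 1.25 times at the others, a log2 difference of 0.27 (95% interval over resampled fish 0.12 to 0.52). With the axis score in the fit the difference was 0.37 (0.32 to 0.49). Segregation may account for it, and no other cause was tested.

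The deviations of Sieg and of the F2 from the mean of the parents were set against each other, since an effect of admixture as such could move both. Across 12771 probes their covariance was 0.0922 (correlation 0.420), above the highest of 100 simulated sets with no deviation and the same parental fish (0.0730, mean -0.0031). With the parents split so that Sieg and the F2 had no parental fish in common, the mean covariance over 4 splits was 0.0446, within the simulated range that reached 0.0591. A shared effect therefore cannot be told apart from the spread of the fish, because the value with separate parents stayed within the simulated range. Of the probes outside both parents, 4 higher and 15 lower ones were common to Sieg and the F2. Another 3 were higher in Sieg and lower in the F2. Independent lists of those sizes would share 1.03 higher and 9.63 lower probes. As Sieg and the F2 were compared with the same parental fish, their lists are not independent and these numbers have no simple chance value. With the parents split in 4 ways, the common lower probes numbered 1, 1, 0 and 4, where independent lists give 1.83, 7.68, 3.84 and 3.38 in that order. The common higher ones numbered 0, 2, 1 and 0, where independent lists give 0.208, 1.64, 0.349 and 0.476.

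The group labels of the fish compared were shuffled over 100 splits, the real one included, and for each of 16 counts fewer than 5 of the 100 splits gave a count as large as the real one, with no correction for the number of counts. Each real count was thus rare among shuffles of single fish, taken one count at a time. For the counts outside both parents and private to Sieg, the shuffles also mixed the species. Except for the rearing count, where rearing was shuffled within populations, rearing stayed with each fish. The shuffles thus kept neither the species difference in those counts nor the link of rearing and group. They therefore cannot exclude chance with these kept. The splits take the fish as separate, although fish of one population or cross were alike (correlation 0.189). With population or cross as a random block the counts were 9 for Sieg outside both parents, 21 for F2 outside both parents, 44 for Sieg against F2, 50 and 359 for Sieg against C. perifretum and C. rhenanus, 633 and 488 for F2 against them and 1569 for the species difference. The splits therefore do not exclude chance differences between populations for any of these counts, and populations as such were not shuffled.

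A count as large came from 1 of 100 splits for the species difference (4190 probes, highest other split 145), for Sieg against C. rhenanus (2810 and 1187), for Sieg against C. perifretum (919 and 488), for probes private to Sieg (69 and 41) and for F2 against C. perifretum (4122 and 2055). The same was found for F2 outside both parents (818 and 37), Broel against Naaf (479 and 216), Laarse Beek against Witte Nete (2350 and 311) and rearing (5039 and 2500). Of the matched comparisons it was found for F2 (1679 and 5) and Sieg (437 and 20) against Naaf and Laarse Beek. The real count was reached by 2 of 100 splits for F2 against C. rhenanus (3506 and 4347), Sieg outside both parents (268 and 580) and F2 against Broel and Witte Nete (103 and 302). It was reached by 4 of 100 for Sieg against F2 (640 and 2418) and for Sieg against Broel and Witte Nete (135 and 785). A few of these other splits called several times the real count, which points to a structure of the fish beyond their groups.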
